A study of Homo sapiens with 4 samples.

How the data were processed

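OCI/AML-2 cells were treated with solvent, ATRA (1e-06 M, once), VPA (0.6 mM every 8 h) or both for 24 h, per the labels, and RNA of each was hybridised to 1 Affymetrix U133A array. One label writes the ATRA dose in a form that could be read as a higher concentration; the dose given here follows the design text. The arrays were grouped by their titles into 4 groups of 1. The authors summarised the probe set signal intensity with MAS 5.0 and scaled each array to a target signal of 150, per the labels and the design text. The deposited intensity values are linear, and their trimmed mean, leaving out 2% at each end, was 150.05 on each of the 4 arrays. Later steps of the authors in MeV 2.2 (total-intensity normalization, centring and log2) were not applied to the values used here. Detection calls were not used here.

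In the order control, ATRA, VPA and ATRA + VPA, 37.2, 37.2, 38.5 and 38.2% of probe sets had signals of 100 or more and 46.0, 46.8, 45.0 and 46.6% lay under 50. The ratio of 3' to 5' probe set signals was 0.82, 0.88, 0.79 and 0.76 for GAPDH and 1.05, 1.04, 1.00 and 1.06 for ACTB. The 18 hybridisation control probe sets had median log2 changes of -0.06 for ATRA, -0.17 for VPA and 0.06 for both against control. For the combination against VPA their median was 0.17 and all 18 were higher (0.05 to 0.41). For the combination against ATRA it was 0.11 (-0.40 to 0.38). The number of arrays limits the precision.

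Of 22283 probe sets 68 were Affymetrix controls and were left out, 19065 named 1 gene, 1043 named several and 2107 had no gene listed. Symbols were looked up by Entrez ID in a RefSeq gene table of assembly GRCh38.p14, used for names only: 19053 probe sets matched, 12 kept the platform's symbol and 0 symbols differed. These name 11963 genes, each represented by its probe set with the highest mean signal. Signals under 50 were set to that floor and log2 changes taken between arrays. A gene was measured in a comparison when its brighter array was at 100 or more (the brightest of 4 for additivity), and it counted as higher or lower from 2-fold. A fold with the dimmer array under the floor is given as at least that size. The comparisons were each drug and the combination against control, the combination against each drug, and the departure of the combination from the sum of the single log2 changes. No test was made: each group has 1 array, and an additive fit to all 4, which would leave 1 residual degree of freedom, was not run.

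The rules for measuring, counting and naming genes, the 36 gene lists and 11 alternatives were fixed before the data were examined. Genes were named by rule: the 10 highest and 10 lowest log2 changes for each comparison with control, and 5 and 5 for each other comparison and for additivity. They were taken from genes at 2-fold or more that lay above the floor on both arrays and had no bright probe set of opposite sign. The 5 largest bounds in each direction, up to 4 members of each list at 2-fold or more, and all members of lists with 15 or fewer measured members or of the submitters' list could be named too. Each list's median was set beside 10000 random lists of equal size matched on mean signal by decile, which describes these arrays and is no p-value. Lists share members, among them 7 genes of the housekeeping and glycolysis lists and 4 of the monocyte and lysosome lists.

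The SD of a log2 change was taken from pairs of probe sets of 1 gene. For VPA against control it was 0.29 at signals of 100 to 300, 0.21 at 300 to 1000 and 0.12 above 1000. Unchanged arrays were simulated 100 times from a separate estimate, the SD of a log2 signal on 1 array. It came from pairs of probe sets of 1 gene in the same signal class, before the floor was set. It was taken as the root mean square of the pairs and, in a model added after the data had been seen, from their median. The former was 0.92 at signals under 25, 0.66 at 25 to 50, 0.38 at 50 to 100 and 0.22 at 100 to 300. Neither model includes variation between cultures. The procedure was tested on simulated data for VPA against control with 11963 genes: all 50 genes at each log2 change of 1.5, 2, -1.5 and -2 passed 2-fold in the right direction (100%), as did 2.58% of 5654 unchanged genes in either direction. The alternatives were a floor of 25 or 100, log2(signal + 50), a minimum of 200 or none, a threshold of 3-fold, the mean over probe sets of a gene, leaving out probe sets of shared or possibly cross-hybridising sequence, median centring, quantile normalization, and signal-dependent centring (loess, span 0.3). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.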

Results

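RNA of OCI/AML-2, an established human acute myeloid leukemia cell line, was measured on 4 Affymetrix U133A arrays, 1 for each of 4 treatments. The cells had received solvent only, all-trans retinoic acid (ATRA, the vitamin A derivative that activates retinoic acid receptors, 1e-06 M), valproic acid (VPA, an inhibitor of histone deacetylases, 0.6 mM every 8 h) or both, and were collected at 24 h. Each group holds 1 array, so there are no replicates. No p-value or standard error is given: a fit that takes the effects of the drugs as additive would leave 1 residual degree of freedom and was not made. Differences between cultures cannot be told from effects of the drugs. All 4 arrays carried values for 22283 probe sets, with median signals of 58.1 for control, 56.6 for ATRA, 61.7 for VPA and 58.5 for ATRA + VPA. The error used here came from different probe sets of the same gene: the SD of a single log2 change was 0.25 for ATRA against control, 0.26 for VPA against control and 0.26 for ATRA + VPA against control, over 1560 pairs of probe sets at a signal of 100 or more. Control and ATRA arrays correlated at r = 0.98 across probe sets, as did VPA and ATRA + VPA arrays, while control and VPA arrays correlated at r = 0.96.

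The comparison of ATRA with control asked which transcripts differ after the retinoid alone. Lists of retinoid response, monocyte and macrophage, interferon response and NADPH oxidase genes had medians above all 10000 matched random lists, and the MYC and ribosome biogenesis list and the heat shock list had medians below all of them. DHRS3, an enzyme that reduces retinaldehyde, was at least 14.1-fold higher, with a signal of 705 against a control reading of 36.3 that lay under the floor of 50. CD1D, which presents lipid antigens, was 10.8-fold higher, SLC2A5, a fructose transporter, 5.45-fold and PSAP, the precursor of the saposins of lysosomal lipid breakdown, 4.90-fold. NCF1, a cytosolic subunit of the phagocyte NADPH oxidase, was 4.51-fold higher, a value that is uncertain because probes for this gene can also bind its near-identical pseudogenes. DTX4 was 4.35-fold higher, the nuclear receptor co-repressor NRIP1 3.60-fold, the inhibitory receptor CD300A 3.58-fold, SLC12A4 3.49-fold, SEL1L3 3.47-fold and the receptor tyrosine kinase MERTK 3.46-fold. HIC1 was at least 5.23-fold higher, CHI3L1 at least 4.81-fold, MYL10 at least 3.75-fold and TLR5, the flagellin receptor, at least 2.69-fold.

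Fewer genes were lower after ATRA. DNAJB1, a co-chaperone of HSP70, was 3.09-fold lower, the AP-1 component JUN 2.70-fold, the transcription factor GATA2 2.56-fold, HOMER3 2.50-fold, DEFB1 2.41-fold, PTGER4 2.34-fold, CDA 2.32-fold, IRS2 2.28-fold, CIB2 2.28-fold and VCAN 2.26-fold. TFAP4 was at least 2.94-fold lower, JOSD1 at least 2.56-fold, BCAT1 at least 2.53-fold, CEND1 at least 2.53-fold and TRIM9 at least 2.34-fold.

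Of 12 measured genes of the retinoid response list, 4 were at least 2-fold higher after ATRA and 0 lower, with a median log2 change of 0.57, above all 10000 matched random lists. Besides DHRS3 and NRIP1 these were CD38, an ectoenzyme of leukocytes, at 2.56-fold and the integrin ITGAX at 2.54-fold. The monocyte and macrophage list had 5 members at least 2-fold higher and 1 lower of 20 (median 0.51, above all 10000 matched random lists). Among 6 NADPH oxidase genes 1 passed 2-fold, NCF1, and the median was 0.63, above all 10000 matched random lists, with log2 changes of 0.87 for CYBA and 0.77 for CYBB. Interferon response genes had 4 of 31 at least 2-fold higher, IRF1 among them at 2.22-fold, and a median of 0.42, above all 10000 matched random lists. The cytokine and chemokine list had a median of 0.23 (3 of 18 members at least 2-fold higher and 1 lower), with the growth factor HBEGF 2.96-fold higher. The lists of MYC network and ribosome biogenesis genes (median -0.35, 0 of 42 past 2-fold), heat shock genes (median -0.41, 1 of 14 at least 2-fold lower) and metallothioneins (median -0.47, 0 of 6 past 2-fold) lay below 0. The first 2 lay below all 10000 matched random lists and the metallothioneins below 9999 of 10000. Mature neutrophil genes had a median of -0.36 with 0 of 8 past 2-fold, and cholesterol synthesis genes a median of -0.23 with 1 of 21 at least 2-fold higher. Smaller medians outside the central 95% of random lists were 0.17 for lysosome genes (3 of 27 at least 2-fold higher), 0.15 for pro-apoptotic genes and -0.13 for replication genes, the last 2 with 0 members past 2-fold. On the arrays that leave out the control, when ATRA was added to VPA, the median of the MYC list was -0.15, of heat shock genes -0.09, of metallothioneins -0.45, of mature neutrophil genes 0.04 and of cholesterol synthesis genes 0.05. The last 2 lists were thus not lower there, and the median of heat shock genes lay near 0.

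In total 92 of 5585 measured genes were at least 2-fold higher after ATRA and 43 at least 2-fold lower, without a test. Arrays simulated with no change gave a mean of 69.6 genes per draw in the higher direction under the noisier of 2 error models, and 13.8 under the other, which was added after the data had been seen; for lower genes these means were 70.3 and 13.8. The 92 higher genes are more than the highest draws of the 2 models, 88 and 24. The 43 lower genes are fewer than the lowest draw of the noisier model, 52, and more than the highest of the other, 22. For lower genes the noisier model thus gives more calls than these arrays did, so it overstates the noise there. With a floor of 100 the counts were 54 higher and 13 lower. CD300A, SLC12A4, MERTK, DEFB1, GATA2, HOMER3, JUN, PTGER4, CIB2 and VCAN were under 2-fold in at least 1 alternative processing, and the other 10 of these 20 ranked genes stayed past 2-fold in every alternative that measured them. In the alternative that reduced them most, CD300A and MERTK had a log2 change of 0, SLC12A4 of 0.16 and JUN of -0.07, so these changes depend on the processing.

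**Figure D1:**
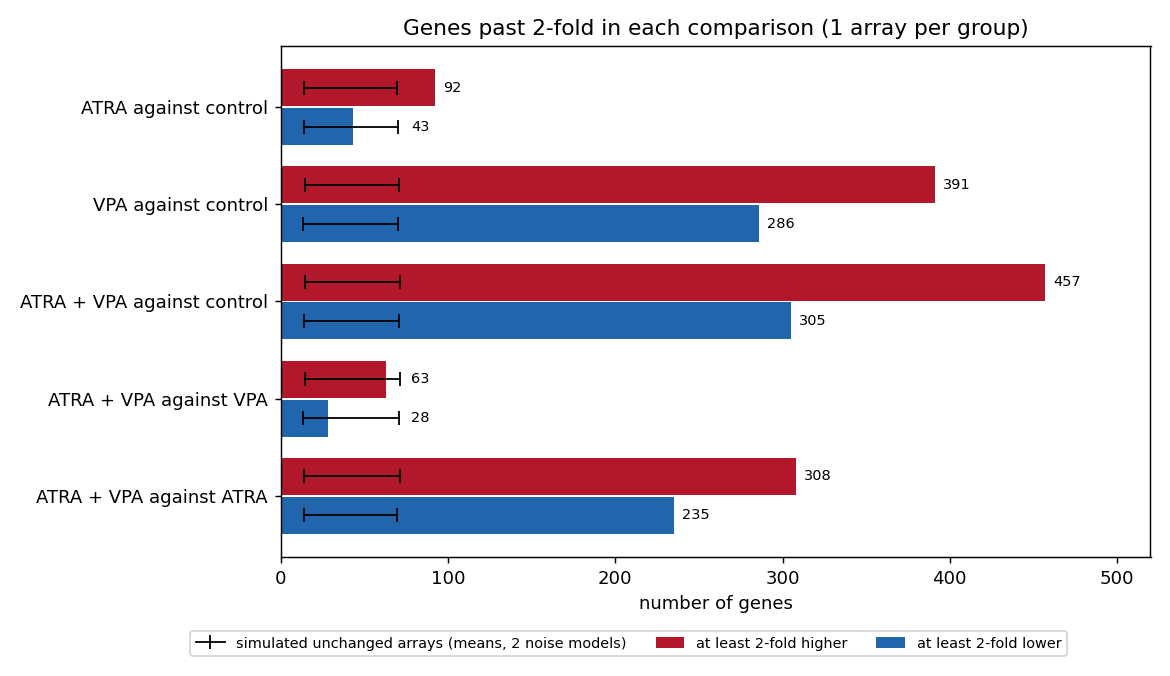
Number of genes (x axis) at least 2-fold higher (red) and at least 2-fold lower (blue) in each of the 5 comparisons (y axis), with 1 array per group. Black lines join the mean counts from simulated unchanged arrays under 2 noise models, about 14 and about 70 genes, and the VPA against control bars, at 391 and 286 genes, reach well past them.

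VPA alone, compared with control to ask which transcripts differ after the deacetylase inhibitor, went with lower signals of MYC and of the lists of ribosome biogenesis, DNA replication and primary granule genes, and with higher signals of MHC class II, lysosome, cytokine and adhesion genes. RGS2, a regulator of G protein signalling, was 12-fold higher, SERPINI1, a protease inhibitor, 10.8-fold, the early response gene IER3 6.45-fold, ITM2C 6.16-fold, RGS1 5.93-fold, ZFP36L1 5.79-fold, the glutamate transporter SLC17A7 5.39-fold, SWAP70 4.97-fold, ADA2 4.97-fold and CREB3 4.90-fold. AKR1C3 was at least 5.20-fold higher, TSPAN13 at least 5.17-fold, SAMSN1 at least 4.41-fold, STAP1 at least 4.30-fold and GPR65 at least 4.04-fold.

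The nucleotide receptor P2RY2 was 9.76-fold lower after VPA, KCNE5 8.07-fold, the chemokine receptor CCR2 7.26-fold, the transcription factor CEBPD 6.79-fold, MYC 5.77-fold, ADI1 5.67-fold, the immunoproteasome subunit PSMB10 5.02-fold, NXF3 4.40-fold, thrombomodulin (THBD) 4.26-fold and TASL 4.2-fold. ALX1 was at least 8.49-fold lower, MS4A6A at least 7.01-fold, VPS52 at least 6.01-fold, MPDU1 at least 4.55-fold and SLC39A4 at least 3.97-fold. In total 391 of 5869 measured genes were at least 2-fold higher and 286 lower after VPA, against simulated means of 70.4 and 70.0 under the noisier model. Of the 20 ranked genes 18 stayed past 2-fold in every alternative processing that measured them. The exceptions were ZFP36L1, which dropped to a log2 change of 0.95 in 1 alternative, and CEBPD, whose only other probe set lay under the floor.

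The list of MYC network and ribosome biogenesis genes had 14 of 41 members at least 2-fold lower and 0 higher after VPA, with a median log2 change of -0.83, below all 10000 matched random lists. Examples beside MYC were PES1 at 3.77-fold, RRP12 at 3.28-fold and MRTO4 at 2.82-fold lower. DNA replication and G1/S genes had 9 of 55 at least 2-fold lower (median -0.52), with thymidylate synthase (TYMS) 3.52-fold, CDC45 2.43-fold and MCM2 2.42-fold lower. G2 and mitosis genes had 3 of 60 at least 2-fold lower, which were CCNA2 at 2.82-fold, FOXM1 at 2.61-fold and AURKB at 2.35-fold, and a median of -0.38. Both medians lay below all 10000 matched random lists. Primary granule genes had 4 of 12 at least 2-fold lower, MS4A3 at 3.71-fold, CLEC11A at 2.58-fold, azurocidin (AZU1) at 2.23-fold and cathepsin G (CTSG) at 2.13-fold, with a median of -0.55, below 9976 of 10000 matched random lists. Heat shock genes had a median of -0.44, below 9963 of 10000 matched random lists, with 1 of 14 at least 2-fold lower, while their medians in the 2 comparisons that leave out the control array were -0.087 for the combination against VPA and -0.007 against ATRA.

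On the higher side after VPA, the MHC class II list had 3 of 6 measured members at least 2-fold higher, with a median of 1.13, above 9986 of 10000 matched random lists. HLA-DQB1 was 3.31-fold higher, HLA-DMB 2.43-fold and the class II transactivator CIITA at least 2.78-fold, while CD74, the invariant chain, had a log2 change of 0.99. HLA-DRB1 and HLA-DOA had log2 changes of 0.06 and -0.25. The CIITA value rests on the VPA reading of 139, against 27.7, 10.2 and 8.9 on the control, ATRA and ATRA + VPA arrays. Lysosome genes had 3 of 28 at least 2-fold higher and a median of 0.52, above all 10000 matched random lists. Cytokine and chemokine genes had 6 of 20 at least 2-fold higher and 3 lower (median 0.36, above 9910 of 10000 matched random lists), with IL1B 4.32-fold higher, CCL20 at least 2.55-fold higher and the inhibitor of NF-kappaB NFKBIA 3.41-fold lower. Adhesion genes and tetraspanins had 6 of 30 at least 2-fold higher and 1 lower (median 0.27, above 9920 of 10000 matched random lists), with CD9 4.49-fold and the integrin ITGB7 2.64-fold higher. Metallothioneins had a median of 0.40, above 9799 of 10000 matched random lists, with 0 of 6 past 2-fold.

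The lists that follow had medians after VPA inside the central 95% of the matched random lists, some with members past 2-fold. Among NADPH oxidase genes, whose median was 0.01, 2 of 6 were at least 2-fold lower, CYBA at 2.05-fold and CYBB at 2.28-fold, and with both drugs the median of this list was 0.10, above 7965 of 10000 matched random lists. Mature neutrophil genes had a median of -0.14, with CEACAM6 3.14-fold, CSF3R 2.09-fold and MNDA 2.07-fold lower and ITGAM at least 3.04-fold higher of 9. Pro-apoptotic genes had a median of 0.24, above 9542 of 10000 matched random lists, with 5 of 27 at least 2-fold higher, among them the death ligand TNFSF10 at 2.33-fold and PMAIP1 at 2.17-fold. The monocyte and macrophage list had a median of 0.18, with 3 of 22 at least 2-fold higher, the co-stimulatory molecule CD86 4.28-fold among them, and 5 lower.

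The other medians after VPA inside that range, with the members at least 2-fold higher and lower, were 0.21 (3 higher and 3 lower of 34) for interferon response genes, 0.08 (2 higher and 1 lower of 11) for retinoid response genes, -0.31 (2 higher and 1 lower of 9) for stem and progenitor genes and 0.13 (3 higher and 2 lower of 26) for myeloid transcription factors. They were -0.26 (0 higher and 1 lower of 6) for erythroid genes, 0.02 (1 higher and 0 lower of 4) for megakaryocyte genes, 0.19 (2 higher and 0 lower of 10) for CDK inhibitors and D cyclins, 0.02 (0 higher and 2 lower of 11) for MHC class I genes, 0.19 (1 higher and 0 lower of 11) for anti-apoptotic genes and 0.27 (2 higher and 0 lower of 11) for p53 targets. Histone genes had -0.23 (0 higher and 0 lower of 9), histone deacetylases and chromatin enzymes 0.14 (1 higher and 0 lower of 25), cholesterol synthesis genes -0.01 (3 higher and 2 lower of 21), fatty acid oxidation genes 0.13 (1 higher and 0 lower of 23) and endoplasmic reticulum stress genes 0.05 (1 higher and 1 lower of 34). Oxidative phosphorylation genes had -0.17 (0 higher and 1 lower of 35), glycolysis genes 0.05 (3 higher and 0 lower of 21), ribosomal protein genes a median of -0.16 and housekeeping genes -0.18. Of 23 measured housekeeping genes and 39 ribosomal protein genes, 0 passed 2-fold in any of the 3 comparisons with control. Few lymphoid markers were measured. Of the B cell list IGKC reached 100 on the control array, with a log2 change of -0.76 after VPA, and FCER2 reached 100 on the ATRA array, at 163 against 82.2 in control. Of the T cell and NK cell list only NKG7 was measured, at least 2.95-fold lower after VPA, below 9934 of 10000 matched random lists of 1 gene, so this list lies outside the central range on a single gene.

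**Figure D2:**
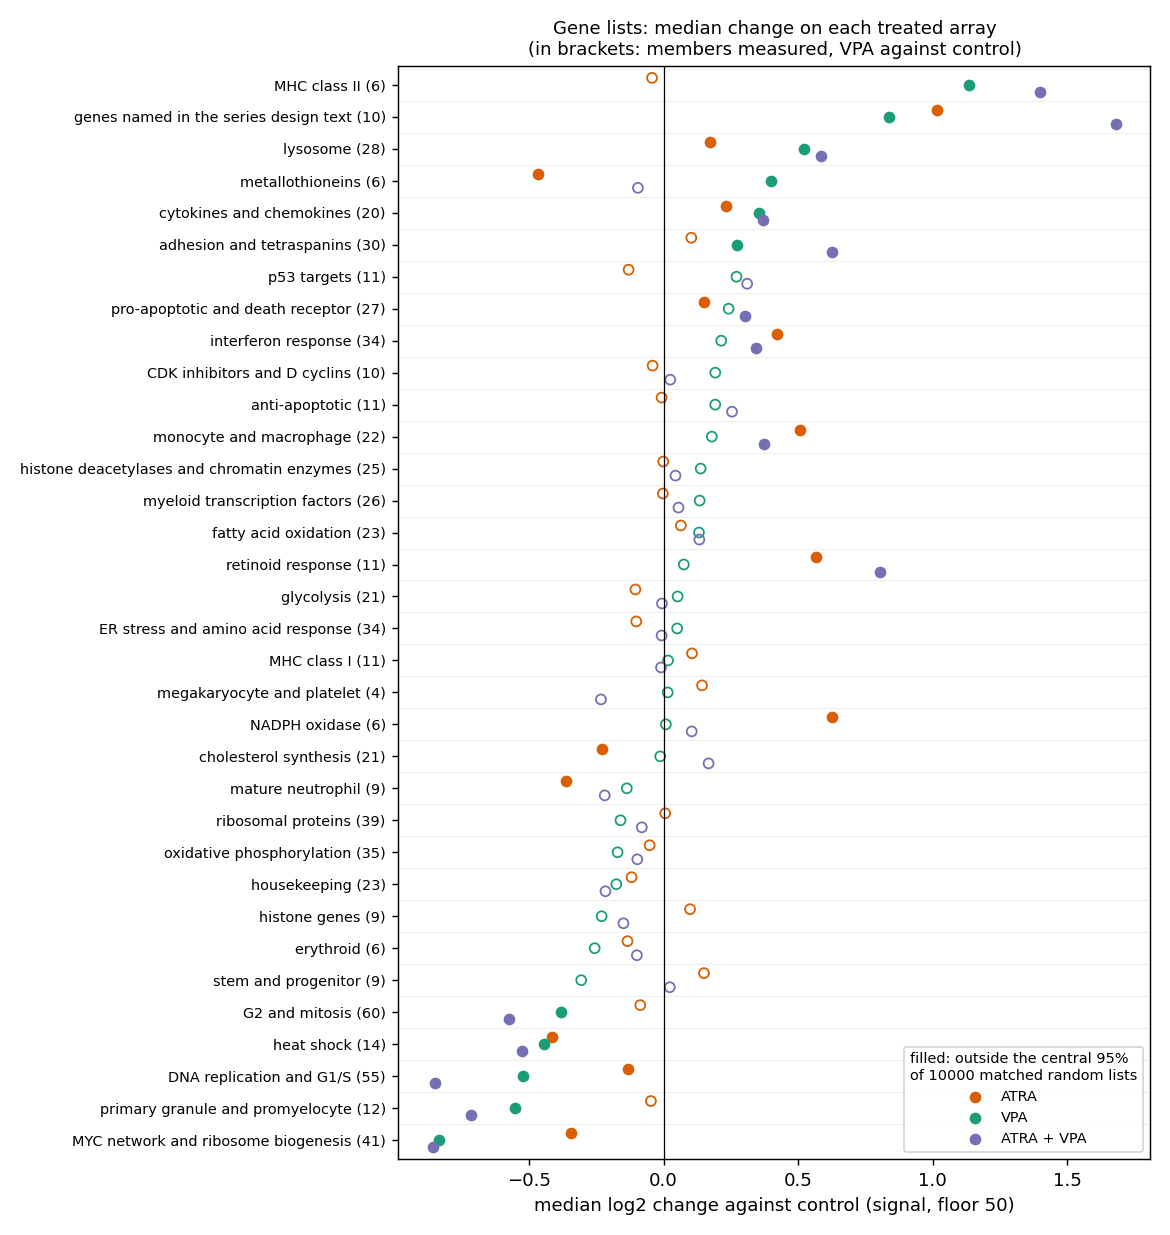
Median log2 change against control (x axis) of 34 of the 36 gene lists (y axis, number of measured members in brackets), for ATRA (orange), VPA (green) and ATRA + VPA (purple), each from 1 array. Filled points lie outside the central 95% of 10000 matched random lists; the DNA replication median moves from -0.13 with ATRA to -0.52 with VPA and -0.85 with both drugs.

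The combination was set against control to ask which transcripts differ with both drugs. Genes that ranked high with VPA alone (RGS2, IER3, SERPINI1) and with ATRA alone (PSAP, SLC2A5, NCF1) were both among the highest. RGS2 was 15.2-fold higher, IER3 9.47-fold, NCF1 8.55-fold, PSAP 8.36-fold, SLC2A5 8.27-fold, SERPINI1 8.21-fold, the MAP kinase phosphatase DUSP6 7.25-fold, RGS16 6.76-fold, the lysosomal fucosidase FUCA1 6.25-fold and SLC17A7 6.18-fold. AKR1C3 was at least 9.84-fold higher, DHRS3 at least 8.50-fold, TSPAN13 at least 7.43-fold, the aryl hydrocarbon receptor AHR at least 5.15-fold and SAMSN1 at least 4.91-fold. ADI1 was 7.05-fold lower, MYC 6.92-fold, CEBPD 6.69-fold, P2RY2 6.53-fold, NXF3 5.84-fold, KCNE5 5.81-fold, ALX1 6.55-fold, VPS52 5.00-fold, carbonic anhydrase CA2 5.08-fold and TYMS 4.99-fold. MS4A6A was at least 7.01-fold lower, NFKBIA at least 5.44-fold, CDC45 at least 4.27-fold, PFAS at least 3.80-fold and FERMT1 at least 3.61-fold. In total 457 of 5841 measured genes were at least 2-fold higher and 305 lower. Of the 20 ranked genes 19 stayed past 2-fold in every alternative that measured them; the exception was CEBPD, for the reason given above.

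Replication genes were lower with both drugs: 21 of 55 were at least 2-fold lower and 0 higher (median -0.85, below all 10000 matched random lists), with GINS2 3.34-fold and MCM2 3.44-fold lower. G2 and mitosis genes had 4 of 60 at least 2-fold lower (median -0.58), the MYC and ribosome biogenesis list 16 of 42 (median -0.86) and primary granule genes 4 of 11 (median -0.72). Adhesion genes and tetraspanins had 10 of 29 at least 2-fold higher (median 0.62), ITGAM at least 4.10-fold and ITGAX 3.64-fold among them, and lysosome genes 7 of 28, with 1 lower (median 0.58), CTSD 3.21-fold and LIPA 2.41-fold among them. Retinoid response genes had 5 of 13 at least 2-fold higher and 1 lower (median 0.80), interferon response genes 6 of 33 higher and 2 lower (median 0.35), and MHC class II genes 3 of 5 higher (median 1.40). Cytokine and chemokine genes had 6 of 20 higher and 2 lower (median 0.37), pro-apoptotic genes 3 of 27 higher (median 0.30) and heat shock genes 2 of 14 lower (median -0.52). The monocyte and macrophage list had a median of 0.37, with 8 of 22 higher and 3 lower, but a median of -0.30 without probe sets of shared or possibly cross-hybridising sequence, so it has no settled direction here.

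The comparisons with control share the control array, so their gene lists overlap by chance, and the overlaps are set beside those of independent lists and of unchanged arrays simulated with a shared control under the noisier and the other error model. These counts take only genes measured in both comparisons, which for ATRA and VPA leaves 62 of the 92 genes higher with ATRA and 213 of the 391 higher with VPA. VPA and the combination had 287 higher genes in common, against 25.4 for independent lists and simulated means of 5.26 and 0.41, and 184 lower genes, against 15.3 and simulated means of 35.6 and 7.50. ATRA and the combination had 54 higher genes in common, against 3.80 and simulated means of 4.87 and 0.33, and 14 lower genes, against 2.40 and simulated means of 35.7 and 7.67. ATRA and VPA alone had 21 higher genes in common, against 2.42 and simulated means of 5.02 and 0.38, and 11 lower genes, against 2.26 and simulated means of 35.5 and 7.48. With the full lists over 6098 genes, independent lists would share 5.90 higher and 2.02 lower genes of ATRA and VPA. The simulated lists averaged about 70 genes per direction under the noisier model and about 14 under the other, shorter than the observed lists of VPA and the combination. Their overlaps are therefore not those that a shared control would give lists of the observed size. Part of each excess may come from the shared control. The lower genes that ATRA shared with VPA and with the combination numbered fewer than the simulated mean under the noisier model and more than it under the other, within the highest of 100 draws (14 in both cases) of that model. With both drugs 134 higher and 114 lower genes passed 2-fold that passed in neither single treatment, which does not show that they differ between treatments.

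The submitters name 12 genes in their design text, and 10 of them were analysed here. They were chosen by the submitters on these samples, so their directions are not independent evidence. After ATRA, VPA and both, log2 changes were -0.82, -2.53 and -2.79 for MYC and -0.25, -1.5 and -1.88 for cyclin A2 (CCNA2). In the same order they were 1.15, 0.13 and 1.58 for IRF1, 1.02, 0.68 and 1.84 for the adhesion molecule ICAM3, 1.08, 1.11 and 2.21 for CEBPB, 2.17, 1.00 and 3.10 for NCF1 and 0.49, -0.11 and 0.04 for NCF4. CD9 had 0.08, 2.17 and 2.10, the first from signals of 72.0 and 68.0 that do not count as measured, the CDK inhibitor CDKN1A -0.15, 1.45 and 1.79, and the CDK inhibitor CDKN2D 1.20, 1.03 and 1.42. Thus 7 of 10 were at least 2-fold higher with both drugs and 2 lower (median 1.68); after ATRA alone 5 of 9 measured were higher, and after VPA alone 4 were higher and 2 lower.

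**Figure D3:**
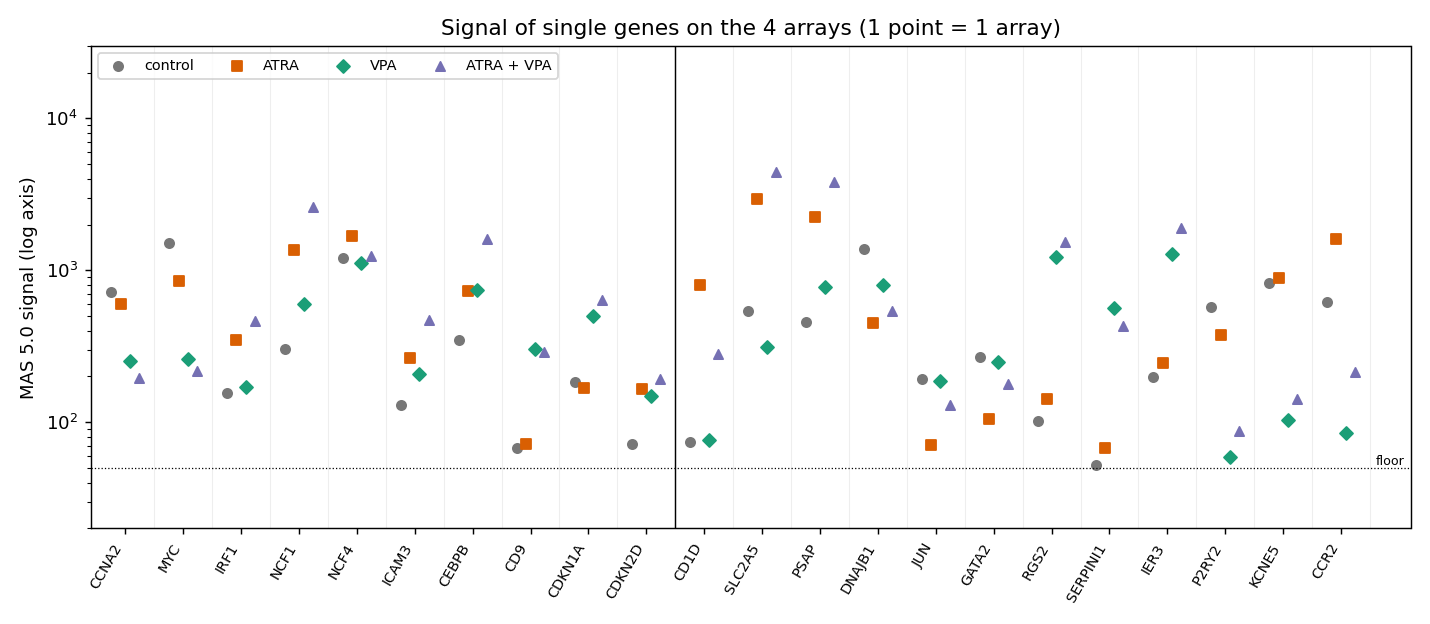
MAS 5.0 signal on a log axis (y) of single genes (x) on the control (circle), ATRA (square), VPA (diamond) and ATRA + VPA (triangle) arrays, 1 point per array, with the floor of 50 dotted. Left of the black line are the 10 genes named by the submitters, right of it the 3 highest and 3 lowest ranked genes of each single drug; MYC stands at 1504 on the control array and 217 with both drugs.

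Adding ATRA to VPA, compared with VPA alone to read the retinoid's effect in VPA-treated cells, went with higher signals of retinoid response and monocyte genes and lower signals of replication genes. SLC2A5 was 14.4-fold higher, THBD 6.40-fold, the chemokine CCL2 6.39-fold, the SRC-family kinase FGR 5.49-fold and PSAP 4.94-fold. DHRS3 was at least 8.50-fold higher, TP53I3 at least 3.16-fold, HIC1 at least 3.01-fold, MYL10 at least 2.35-fold and UPP1 at least 2.33-fold. The replication factor MCM10 was 3.20-fold lower, RGS1 2.84-fold, PUS7L 2.51-fold, ADM 2.41-fold and SFTPB 2.23-fold, ZBTB40 at least 2.94-fold, SPDEF at least 2.26-fold, HABP4 at least 2.39-fold and CIITA at least 2.78-fold. KAT8, at least 2.84-fold lower by its brightest probe set, had a log2 change of 0.33 without probe sets of shared sequence. MCM10, PUS7L and SFTPB were under 2-fold in at least 1 alternative, with SFTPB falling to a log2 change of 0. Retinoid response genes had a median of 0.44 and monocyte genes of 0.38, both above all 10000 matched random lists, and replication genes a median of -0.33 with 1 of 48 at least 2-fold lower. Medians were 0.27 for NADPH oxidase genes, 0.22 for interferon response genes, 0.15 for pro-apoptotic genes, -0.19 for G2 and mitosis genes and -0.11 for endoplasmic reticulum stress genes, all outside the central 95%. In total 63 of 5709 genes were at least 2-fold higher and 28 lower. The higher count lay below the 71.1 genes of the noisier simulation and above the 14.4 of the other. The lower count lay below the lowest draw of the noisier simulation, 49, and above the highest of the other, 23. The split was 81 higher and 12 lower after signal-dependent centring, 46 and 5 with a floor of 100, and 32 and 6 on log2(signal + 50).

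Adding VPA to ATRA, compared with ATRA alone to read the effect of VPA in ATRA-treated cells, went with the genes that ranked high and low with VPA alone. RGS2 was 10.9-fold higher, IER3 7.68-fold, SERPINI1 6.36-fold, SLC17A7 5.51-fold and IL1B 5.05-fold. TSPAN13 was at least 7.43-fold higher, AHR at least 5.15-fold, RIPOR2 at least 4.39-fold, TRIM9 at least 4.26-fold and WIPI1 at least 3.90-fold. CCR2 was 7.46-fold lower, KCNE5 6.19-fold, ADI1 6.17-fold, VPS52 5.99-fold and CEBPD 5.88-fold, while MS4A6A was at least 10.3-fold lower, NFKBIA at least 6.38-fold, CD209 at least 4.75-fold, CDC45 at least 3.36-fold and FCER2 at least 3.26-fold. Replication genes had 14 of 50 at least 2-fold lower with a median of -0.73, and MHC class II genes 2 of 4 higher with a median of 1.19. Medians were -0.55 for the MYC list, -0.49 for G2 and mitosis genes, -0.59 for primary granule genes and 0.29 for lysosome genes, all outside the central 95%. In total 308 of 5797 genes were at least 2-fold higher and 235 lower, and 9 of the 10 ranked genes, all but CEBPD, stayed past 2-fold in every alternative that measured them.

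Each drug's change was read on arrays that did not serve to pick the genes. Across 6098 genes, which are not independent replicates, the VPA change without ATRA and with ATRA correlated at r = 0.77 (rho = 0.72), and 192 higher and 127 lower genes were in common, against 19.7 and 11 for independent lists. The ATRA change without and with VPA correlated at r = 0.34 (rho = 0.26), with 31 shared higher genes against 0.95 and 0 shared lower genes against 0.20. The 391 genes higher with VPA alone had a median of 1.27 there and 0.99 when VPA was added to ATRA. The 92 genes higher with ATRA alone had 1.24 there and 0.70 when ATRA was added to VPA, 79 of them in the same direction, while the 43 genes lower with ATRA alone had -1.15 and -0.14. The mean ATRA change and the mean VPA change correlated at r = 0.08 (rho = 0.12). ATRA against control and VPA against control correlated at r = 0.32, against 0.50 for unchanged arrays that share a control under the noisier model. Their covariance was above the simulated one, 0.0759 against 0.0609, so the lower r does not show opposed effects of the drugs.

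**Figure D4:**
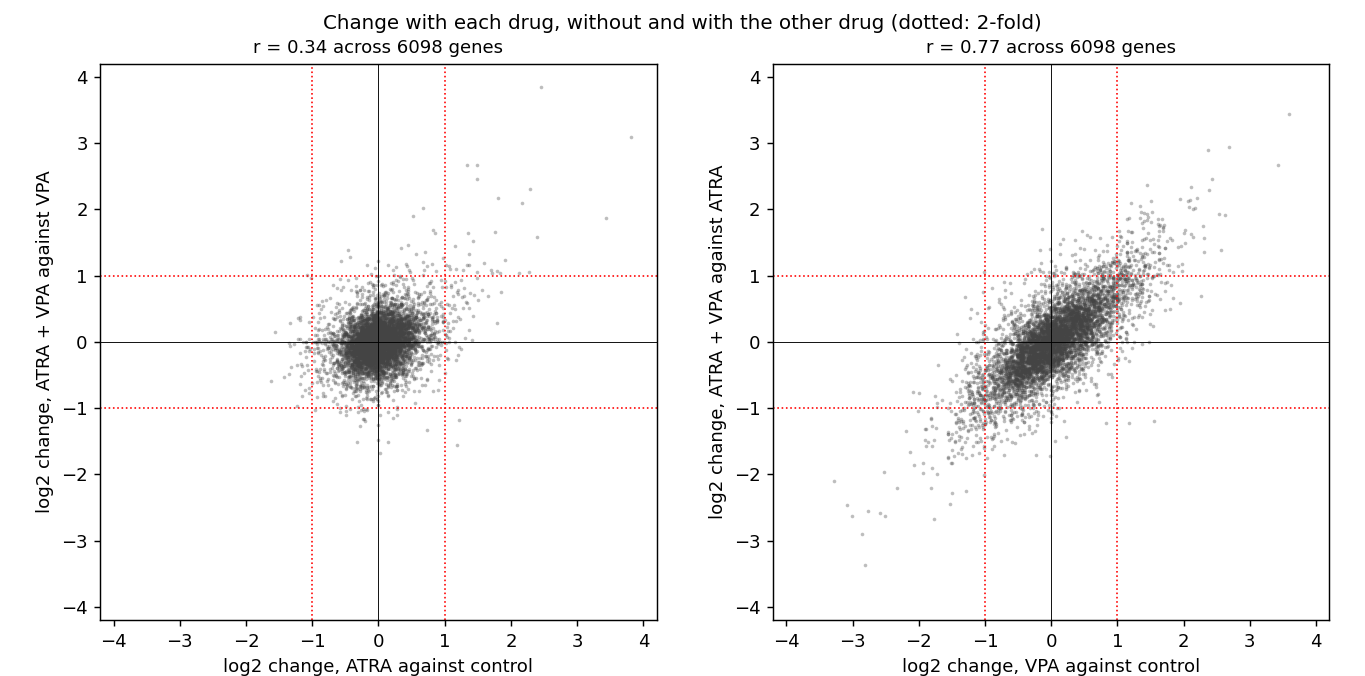
Log2 change of each of 6098 genes (points) with ATRA (left) and VPA (right), without the other drug (x axis) and with it (y axis), from 1 array per group; dotted lines mark 2-fold. The VPA cloud follows the diagonal (r = 0.77), and the ATRA cloud is round apart from genes in the upper right (r = 0.34).

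Genes past 2-fold in opposite directions with the single drugs numbered 6, and they are named here after their values were seen. THBD was 2.54-fold higher with ATRA and 4.26-fold lower with VPA, and its signal with both drugs was 821 against 547 in control. CCR2 was 2.58-fold higher with ATRA, 7.26-fold lower with VPA and 2.90-fold lower with both. FGR (log2 changes of 1.49 and -2.02), CCL2 (1.49 and -1.04) and COL8A2 (1.59 and -1.11) had the same pattern, and TRIM9 the reverse, at least 2.34-fold lower with ATRA and 2.31-fold higher with VPA.

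The design also asks whether the combination equals the sum of the single log2 changes. Of 6098 genes 90 lay at 1 or more above the sum and 72 at 1 or more below it. Among genes read at the floor or above on all 4 arrays, with no bright probe set going the other way, TOR1AIP2 stood furthest above, by 2.08, followed by MYL4 (1.98), CEP72 (1.85), CDYL (1.71) and CIB2 (1.56). PUS7L stood furthest below, at -2.06, followed by MCM10 (-1.70), CINP (-1.63), EPHX1 (-1.57) and CD1D (-1.56), the last with signals of 797 after ATRA and 282 after both. These counts are below the 182 and 182 genes that unchanged arrays gave under the noisier model and above the 49.1 and 48.3 of the other. They are also below the lowest draws of the noisier model, 150 and 144, so that model overstates the noise here. The highest draws of the other model were 65 and 66. Of the 162 genes 135 had no further bright probe set that could check the reading. Of the 10 named genes 3, TOR1AIP2, CEP72 and CD1D, stayed past 2-fold in every alternative. Among lists, heat shock genes (median 0.35) and MYC and ribosome biogenesis genes (median 0.27) lay above the sum, higher than 9998 and 9999 of 10000 matched random lists, and cholesterol synthesis genes (0.20) and oxidative phosphorylation genes (0.15) lay above it by less. A control array that stands apart would also give a list a departure above the sum, so these medians do not show an interaction of the drugs. Below the sum lay lysosome genes (median -0.19, below 9987 of 10000 matched random lists), replication genes (-0.18, below 9975 of 10000 matched random lists), G2 and mitosis genes (-0.13, below 9949 of 10000 matched random lists) and interferon response genes (-0.17, below 9854 of 10000 matched random lists). Lysosome and interferon response genes were higher on each treated array, which a control array reading low for them would also give. Any 1 array that stands apart can move a departure in either direction, so the medians below the sum do not show an interaction either.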

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

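Of the tests given here only the signal-dependent centring of the heat shock list was chosen before its result was seen. All other tests and the bounds they were held to were chosen after, and the use of intervals and the division of the third pattern by probe sets were added once values had been seen.

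The first pattern is in heat shock genes, whose median lay below 0 on each treated array against control, at -0.41 with ATRA, -0.44 with VPA and -0.52 with both. Signal-dependent scaling between arrays is argued against, since the median with ATRA was -0.39 after that centring. The 2 comparisons that leave out the control array had medians of -0.087 and -0.007, which is what a control array or control culture standing apart would give. A lowering by each drug without adding up predicts a departure from additivity above 0, and the median was 0.35, which the first explanation gives as well. With 1 control array the 2 cannot be told apart, and a drug effect on these genes stays possible but untested.

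The second pattern is that the 43 genes lower with ATRA alone had a median of -1.15 there and -0.14 when ATRA was added to VPA (95% interval over resampled genes -0.35 to -0.03, 29 of 43 genes below 0). Most of the size may therefore come from chance extremes of the readings that chose the genes. The interval leaves out 0, but such intervals resample genes read on the same arrays and hold no variation between arrays or cultures. In VPA against control, which shares the control array, the same genes had a median of -0.47 (interval -0.79 to -0.22), short of the -0.86 set for a control that stands apart and nearer 0 than the -0.57 set against it, though the interval takes in the latter. Unchanged arrays that share a control correlate at 0.50 in these 2 comparisons, so noise of the control readings alone would carry part of the lowering over. The value therefore does not decide whether the control is the main source. With 1 control array a part of the pattern from it cannot be told apart from effects of VPA on these genes. A response to ATRA that VPA prevents stays open and untested.

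The third pattern is the 162 genes at 2-fold or more from additivity. Of these 135 have no further bright probe set, so noise of a single dim reading cannot be told apart from an interaction there. For the 27 others 27 of 32 further probe sets (84.4%, exact 95% interval 67.2 to 94.7) departed in the same direction, against 195 of 200 for VPA against control, which argues against noise of single probe sets in those genes. The interval takes probe sets on the same 4 arrays as independent and holds no variation between arrays or cultures. Among genes at 100 or more on all 4 arrays 45 passed, against simulated means of 46.5 under the noisier model and 8.46 under the other, so an interaction of the drugs in well-measured genes stays open, as does variation between cultures.

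SPDEF, TOR1AIP2 and ZBTB40 passed 2-fold in opposite directions for the same drug without and with the other, a difference that was not tested. SPDEF had log2 changes of 1.22 with ATRA without VPA and -1.17 with it, and 1.17 with VPA without ATRA and -1.22 with it, from signals of 26.5, 116, 113 and 37.3 on the control, ATRA, VPA and ATRA + VPA arrays. In the same order TOR1AIP2 had -1.07, 1.01, -1.02 and 1.06 from signals of 253, 120.1, 124 and 251, and ZBTB40 1.19, -1.56, 1.56 and -1.19 from signals of 34.3, 114, 147 and 43.5. SPDEF and ZBTB40 were under the floor of 50 on the control and ATRA + VPA arrays, so their values are bounds.

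Among probe sets that name no single gene, and so entered no comparison, 4 stood at least 4-fold above control, 1 of them with ATRA, 1 with VPA and 4 with both drugs. A probe set that names several genes, with a signal of 317 in control, had a log2 change of 2.16 with ATRA and 3.18 with both drugs. A probe set with no gene listed, with 81.8 in control, had 2.17 with VPA and 2.16 with both, another with no gene listed, with 56.1 in control, had 2.15 with both, and a further one, with no gene listed, with 109 in control, had 2.14 with both. In the other direction 1 probe set that names several genes was at least 4-fold below control with VPA, at 143 against 582, a log2 change of -2.02.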

How the results depend on the processing

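Replicates could not be paired across groups because each group holds 1 array. An additive fit, which would set each drug's change without the other drug beside its change with it and leave 1 residual degree of freedom, was not made. All alternatives were fixed in advance except the noise model of the simulated arrays taken from the median of probe set pairs, which was chosen after seeing the data. Of the gene list medians 1860 moved by less than 1 SD of the medians of their matched random lists, a spread between genes that is wide for short lists, 263 moved by more and 2 reversed. Of the values of named genes, held to the spread between probe sets, the numbers were 1568, 326 and 1, of the counts of genes 73 stayed within 1.5 times and 59 moved, and of the correlations 17 stayed within 1 SD over resampled genes and 13 moved. The minimum signal does not enter the log2 change of a gene. The 196 values of named genes under a minimum of 200, and the 196 under none, therefore stayed by construction. The list medians were not equally stable under all alternatives. Without probe sets of shared sequence 84 moved, 1 reversed and 121 stayed, and without a minimum 61 moved and 153 stayed. Under median centring 0 moved and 214 stayed. Median centring and quantile normalization moved no count by over 1.5 times. Without a minimum signal the 2-fold counts cannot change, since a 2-fold gene above the floor already reaches 100. With a floor of 25 they cannot change either, since a measured gene whose dimmer array lies under 50 already passes 2-fold. In both alternatives these counts therefore stayed by construction, while the counts for additivity could move. A stricter floor, minimum or threshold, or a pseudocount, lowers counts by construction; for the other shifts the cause was not tested. Arrays limit precision through signals near the background: 46.0% of probe sets on the control array lay under 50.

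With a floor of 100 the counts were 54 higher and 13 lower for ATRA against control, 223 higher for VPA against control, 284 higher and 195 lower for the combination against control, 5 lower for the combination against VPA, 182 higher and 144 lower for the combination against ATRA, and 32 above and 25 below additivity; a minimum of 200 gave the same 2-fold counts and 33 above and 25 below additivity. On log2(signal + 50) they were, for the 5 comparisons in that order and then additivity, 43 and 14, 185 and 134, 238 and 143, 32 and 6, 139 and 111, and 30 and 23. At 3-fold they were 19 and 1, 76 and 38, 110 and 46, 16 and 1, 58 and 41, and 7 and 6. The mean over probe sets gave 24 lower for ATRA, 41 higher and 17 lower for the combination against VPA and 55 above additivity. Without probe sets of shared sequence 22 were lower for ATRA, 250 higher and 160 lower for VPA, 301 and 159 for the combination, 41 and 15 against VPA, 188 and 132 against ATRA, and 59 above additivity. Signal-dependent centring gave 12 lower for the combination against VPA.

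The correlation of ATRA changes, 0.344, was 0.372 with a floor of 100, 0.379 on log2(signal + 50), 0.466 with a minimum of 200, 0.370 with the mean over probe sets and 0.299 without a minimum. That of VPA changes, 0.766, was 0.780, 0.781, 0.830, 0.788 and 0.721. That of the mean effects, 0.084, was 0.104 with a minimum of 200, 0.031 with signal-dependent centring and 0.067 with a floor of 25. The spread between probe sets, 0.255, was 0.239 with a floor of 100, 0.204 on log2(signal + 50), 0.208 with a minimum of 200 and 0.274 without probe sets of shared sequence. The pro-apoptotic list in the combination against VPA turned from 0.15 to -0.00853 with a minimum of 200. Without probe sets of shared sequence the monocyte list in the combination turned from 0.37 to -0.30 and KAT8 in the combination against VPA from -1.51 to 0.33; the cause was not tested.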

Other observations

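The test in this part and its bound were chosen after its result had been seen.

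Cholesterol synthesis genes had a median log2 change of -0.23 with ATRA, -0.01 with VPA and 0.17 with both drugs, and of 0.37 when VPA was added to ATRA (2 of 22 at least 2-fold higher, above 9952 of 10000 matched random lists). Metallothioneins, which bind metal ions, had -0.47 with ATRA and -0.45 when ATRA was added to VPA, the latter below 9998 of 10000 matched random lists, with 0 of 6 members past 2-fold. Glycolysis genes had a median of -0.14 when ATRA was added to VPA (below 9951 of 10000 matched random lists). Adhesion genes and tetraspanins had 0.23 in that comparison (above 9999 of 10000 matched random lists) and 0.30 when VPA was added to ATRA.

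A hypothesis is that the genes raised by ATRA respond to it with and without VPA. Genes at least 2-fold higher with ATRA alone had a median of 0.70 when ATRA was added to VPA, 85.9% of 92 above 0, and genes at least 2-fold higher in that comparison had 0.98 with ATRA alone, 87.3% of 63 above 0. The sizes where the genes were picked were 1.24 and 1.18, which picking inflates. Both medians exceed 0.5 of the size where picked, a bound set with these values already known, so the data are consistent with the hypothesis but did not test it independently.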
